A study of Mus musculus with 2 samples.

How the data were processed

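Total RNA from the colons of male ICR mice, an outbred stock, was labelled with biotin and hybridised to whole-transcript expression arrays, per the labels' protocols. The series holds 2 arrays. One carried RNA of mice fed a control diet, and the other RNA of mice fed a diet with 10% psyllium, a viscous seed-husk fibre, for 5 days. The mice were 7 weeks old. The labels do not say how many mice contributed RNA to each array, which part of the colon was taken, or whether its muscle layers were kept. Each diet has 1 array, so no comparison has a replicate check, and no standard error or p-value is given.

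The deposited table holds a normalised intensity per probe set on a linear scale. RMA and Affymetrix Expression Console are named, without versions, in the submitters' processing notes. RMA as usually run corrects background, equalises the arrays' probe distributions and summarises the probes of a set by median polish. Whether the deposited intensities are the antilogarithm of RMA's output is not given in the sources used here, and neither is the annotation the authors used. The fixed plan assumed log2 values. The deposited intensities were therefore converted to log2, with no pseudocount since all were above 0. They ran from 1.92 to 13675 on the control array, with a median of 48.9, and from 1.76 to 13841 on the psyllium array, with a median of 49.8. For 1013 of the 41345 probe sets (2.45%) the 2 deposited values were identical. The number of arrays limits the precision. If the arrays were equalised in this way, every difference is relative to the bulk of transcripts, and a change in total RNA per cell is not visible.

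Probe sets were named from GEO's platform annotation, with symbols looked up by gene number in a RefSeq gene table of assembly GRCm38.p6. That table held 23328 of the 23521 probe sets naming 1 gene, and the other 193 kept the platform's symbol. A further 1814 probe sets named several genes and 16010 named none here. They stayed out of the gene comparison. For the 1082 of 22180 genes with several probe sets, the one with the highest mean over both arrays was used. No genome build is named in the files, so no coordinates are given.

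The difference for a gene was its log2 intensity on the psyllium array minus that on the control array. Counts at 2-fold used the 11090 genes whose higher value was at or above the median of that quantity, an intensity of 69.5. A gene passes on its brighter array alone, so the fold of a gene that is dim on the other array is uncertain. This also holds for Reg1, Scnn1b, Klrd1, Cd163, Mcpt1 and Defa24. Between probe sets of the same gene, both past this filter, the 2 differences correlated across 332 genes with Pearson's r = 0.36. Their median absolute gap was 0.17 on the log2 scale. This measures agreement between probe sets on the same RNA, not between animals, and genes are not independent replicates.

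Before the data were examined, 39 gene lists were fixed, covering pathways, epithelial lineages, immune cells, wall cells and tissues that could contaminate a colon sample. Of their 760 members 682 were measured by a probe set naming that gene alone, older symbols being matched through the RefSeq table. A gene in several lists is counted in each. Of measured absorptive colonocyte genes 6 of 22 also belong to another fixed list. The same holds for 3 of 23 ion and water transport genes and 2 of 22 xenobiotic metabolism genes. Lists that share genes are therefore not separate findings. For the 38 lists with at least 5 measured members, the list's median difference was placed among the medians of 10000 random lists of the same size. These were matched on mean expression in 20 bins. A list stood apart when its median lay outside the central 95% of those medians. This describes the 2 arrays and is not a test of the diets, and genes that vary together widen the true range. Members were counted as higher or lower at 1.5-fold. Pan-epithelial genes, YAP and TEAD targets and 2 arms of the clock were added as lists after the fixed lists had been seen.

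The rule for named genes, also fixed beforehand, took the 12 largest differences in each direction past the filter. It left out predicted and clone-named genes, olfactory and vomeronasal receptors, small RNAs and antigen-receptor segments. Of each list it took up to 4 members past the filter with the largest difference of at least 1.5-fold, or else up to 2 members with the highest level.

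The procedure was tested on simulated data for this comparison, made from the 22180 genes by shuffling their differences among genes of like expression. Known folds were then added to 200 genes past the filter. At 2-fold it recovered 93.3% of genes raised 2.5-fold and 95.3% of genes lowered 2.5-fold, and 100% and 92.3% of those raised and lowered 3-fold. Of 200 unchanged lists of 18 genes it placed 7.5% outside the 95% range, where 5% are due by chance. It placed 100% of lists shifted by 0.4 on the log2 scale above the range. That shift is large beside the spread of random medians (SD 0.061 for the smooth muscle list), and smaller shifts were not tried. The simulated lists were drawn from the same brighter genes, so these rates do not describe lists of mostly dim members.

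Alternatives fixed beforehand were no filter and a filter at the 75th percentile, thresholds of 1.5-fold and 3-fold, and further quantile normalisation. Others were removal of a lowess trend of the difference with intensity (span 0.3), centring on the median difference, the mean of a gene's probe sets, and genes with a single probe set only. For lists they were also members past the filter only, unmatched random lists, and the mean in place of the median. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.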

Results

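Gene expression was measured in the colon of mice fed a control diet or a diet with 10% psyllium for 5 days, on 1 array per diet. The comparison asks which colonic transcripts differ after a short period on the fibre. Values are log2 differences, psyllium minus control, of normalised intensities. Neither diet has replicate arrays, so every difference is between these 2 arrays only and carries no error of its own. Over the 11090 genes past the intensity filter the 2 arrays correlated across genes with Pearson's r = 0.97. The differences had a median of -0.04 and an SD across genes of 0.33, and 93.6% of genes differed by less than 1.5-fold.

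The 12 largest positive differences included genes of the extracellular matrix and of muscle, and the 12 largest negative ones included esterases, a water channel and antimicrobial genes. Past the filter 117 genes were at least 2-fold higher on the psyllium array and 57 were at least 2-fold lower. The highest difference was that of Ccn3, a matricellular protein, at 6.53-fold (intensity 157 on the control array and 1022 on the psyllium array). Fibronectin, Fn1, was 6.10-fold higher (404 and 2464), Cilp 6.18-fold (27.2 and 168) and Ctla2a 6.17-fold (57.7 and 356). The fibronectin receptor subunit Itga5 was 4.68-fold higher, the proteoglycan versican, Vcan, 4.54-fold, and the microfibril protein Mfap5 4.86-fold. The muscle genes Ankrd1, Actc1 and Actg2 were 5.22-fold, 4.82-fold and 4.42-fold higher. Vip, the neuropeptide vasoactive intestinal peptide, was 4.70-fold higher and C1qtnf3 4.48-fold. On the control array Cilp, Ctla2a, Ankrd1, Mfap5, Actc1 and Vcan lay below the filter's intensity of 69.5, so their folds rest on a dim value and neither their size nor their rank is certain.

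On the opposite side the carboxylesterase Ces2a was 7.47-fold lower (784 and 105), and its relatives Ces1g and Ces2b were 3.64-fold and 3.46-fold lower. The water channel Aqp8 was 6.07-fold lower (306 and 50.5). The psyllium values of Aqp8 and of Sprr1a (40.8) lay below the filter's intensity, so the size of these folds is uncertain. Clca4a and Clca4b were 4.23-fold and 4.14-fold lower. The mean of the 2 probe sets of Clca4a gave a smaller difference of -1.13, since the other one differed little. That other probe set lay below the filter's intensity on both arrays, so it says little about the gene. The epithelial gene Sprr1a and the sugar phosphate transporter Slc37a2 were 4.26-fold and 4.24-fold lower. The acute-phase gene Saa3 was 3.40-fold lower, intestinal alkaline phosphatase, Alpi, 3.28-fold, Akr1c18 3.20-fold, and the antibacterial lectin Reg3g 3.12-fold (2511 and 806). The Ces, Clca4 and actin genes have close relatives, and the values of such genes are uncertain where probes bind more than 1 of them.

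**Figure D1:**
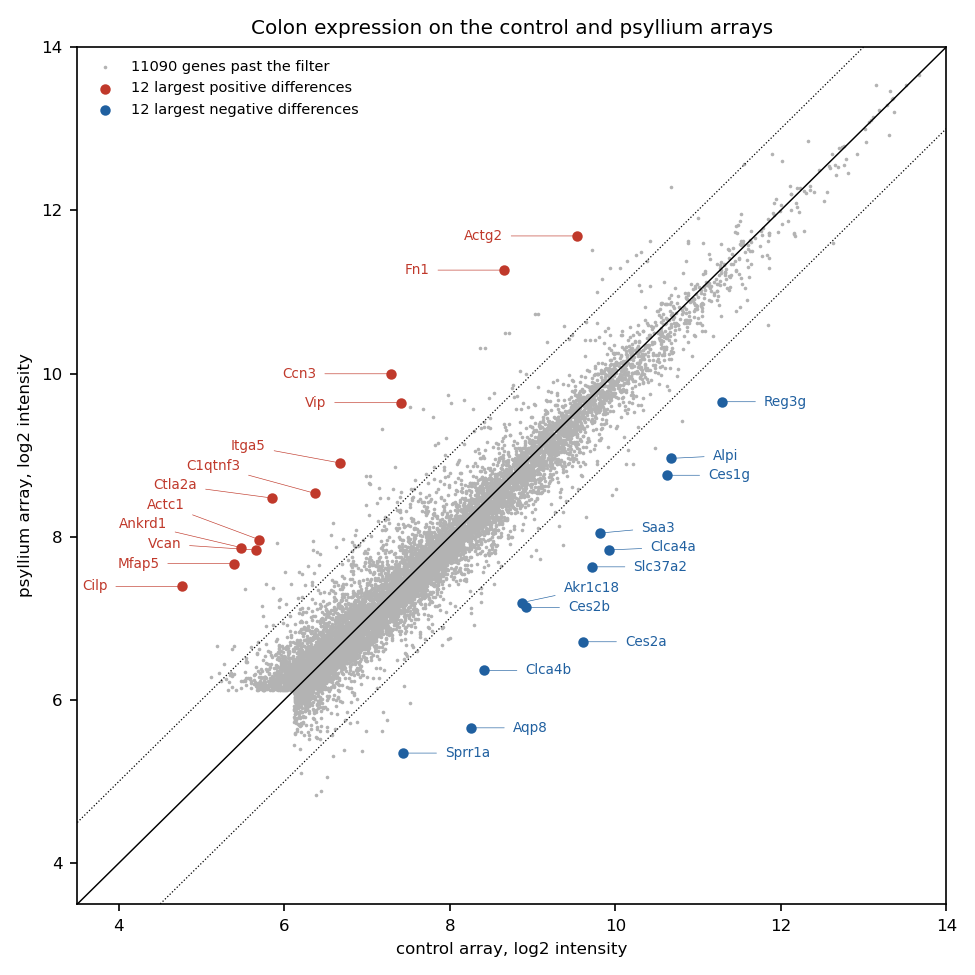
Log2 intensity on the psyllium array (vertical axis) against the control array (horizontal axis) for 11090 genes past the filter, 1 point per gene, with the 12 largest differences in each direction coloured and named. The solid line marks equal values and the dotted lines 2-fold differences; Ces2a lies farthest below and Ccn3 farthest above.

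Of the 38 gene lists with enough measured members, 7 lay above the central 95% of matched random lists, 16 below it and 15 inside it. For 5 of the 7 and 9 of the 16 this held under each of the alternatives run. Where all members of a list were past the filter, the alternative on such members repeats the main value and adds no check. This was so for the endoplasmic reticulum stress, goblet, absorptive colonocyte, smooth muscle and oxidative phosphorylation lists.

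**Figure D2:**
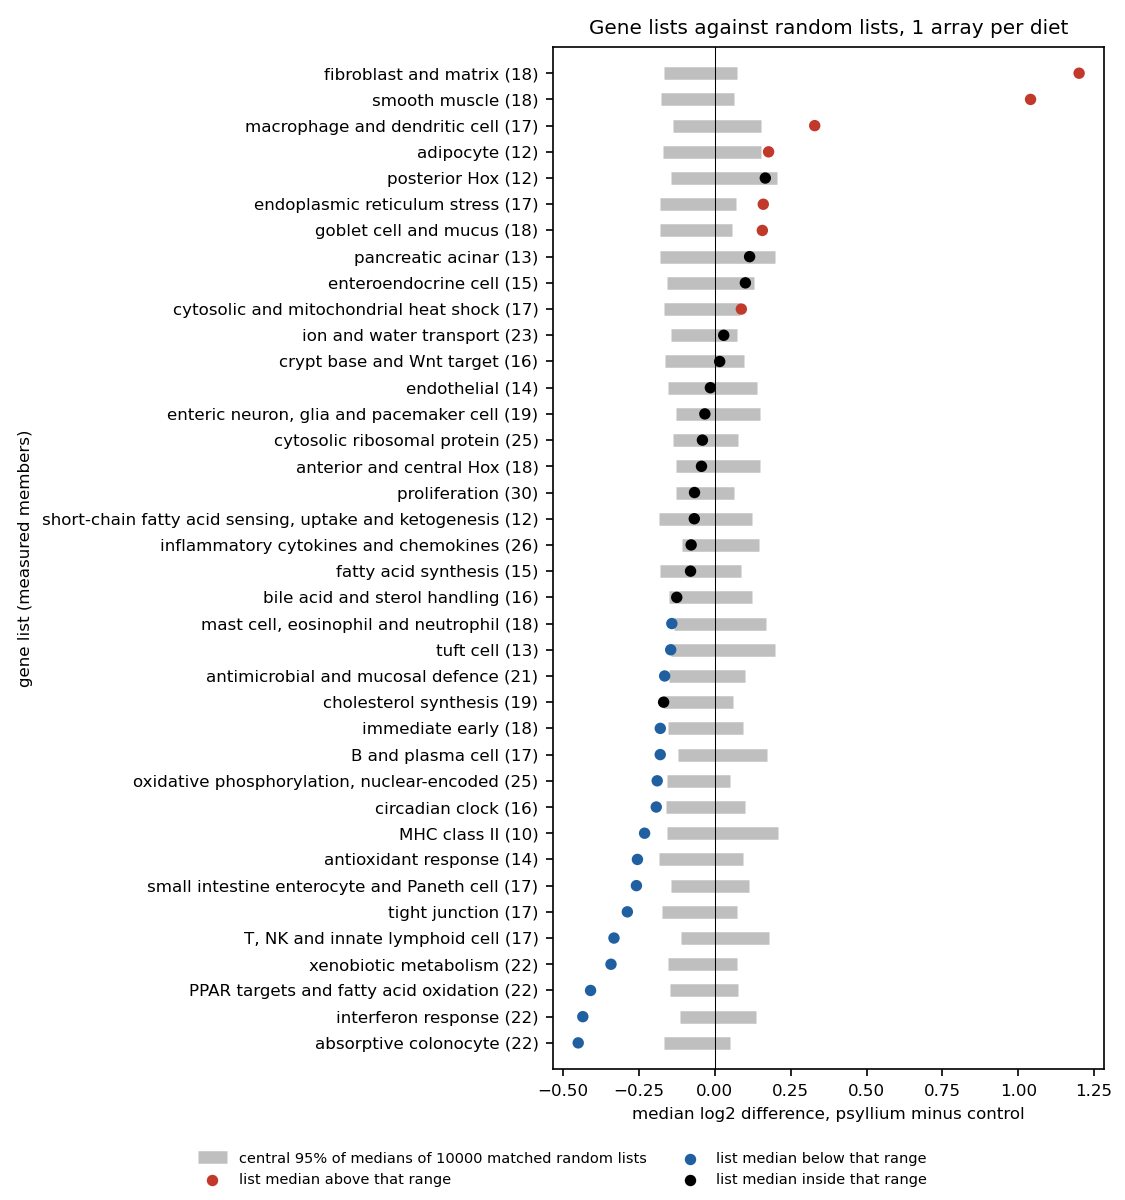
Median log2 difference, psyllium minus control (horizontal axis), of 38 gene lists (vertical axis, with the number of measured members), 1 dot per list. Grey bars span the central 95% of medians of 10000 random lists matched on expression; fibroblast and matrix genes (1.20) and smooth muscle genes (1.04) lie farthest to the right, absorptive colonocyte genes (-0.45) farthest to the left.

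Smooth muscle and connective tissue genes were higher on the psyllium array nearly throughout. Of 18 smooth muscle genes 17 were at least 1.5-fold higher and none lower, with a median difference of 1.04 (2.06-fold) and a range from 0.58 to 2.14. Actg2, the enteric smooth muscle actin, was followed by the intermediate filament genes Synm (3.69-fold) and Des (3.45-fold) and the actin-binding Cald1 (3.24-fold). Of 18 fibroblast and matrix genes 16 were at least 1.5-fold higher and none lower, with a median of 1.20 (2.30-fold). After Fn1 came Lum (4.40-fold) and the fibrillar collagens Col3a1 (3.44-fold) and Col1a1 (3.39-fold). Both medians lay above those of all 10000 random lists.

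Endothelial and enteric nerve genes lay inside the random range, and macrophage genes lay above it by less than the muscle genes. The endothelial list had a median of -0.01 and a mean of 0.12, with 1 of 14 members, the lymphatic marker Lyve1 (2.09-fold), past 1.5-fold. Enteric neuron, glia and pacemaker genes had a median of -0.03 and a mean of 0.09, and Vip was the 1 member of 19 past 1.5-fold. Adipocyte genes had a median of 0.18, just outside the random range, with 1 of 12 members at least 1.5-fold higher (Car3, 1.51-fold). That position was lost under 4 of 6 alternatives, and on members past the filter the median was 0.046. Macrophage and dendritic cell genes had a median of 0.33, above the random range of -0.14 to 0.15, and 15 of 17 had positive differences. Mrc1 (2.33-fold) and Cd163 (1.71-fold), both scavenger receptors of resident macrophages, were the 2 past 1.5-fold. This position held under 6 of 6 alternatives.

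**Figure D3:**
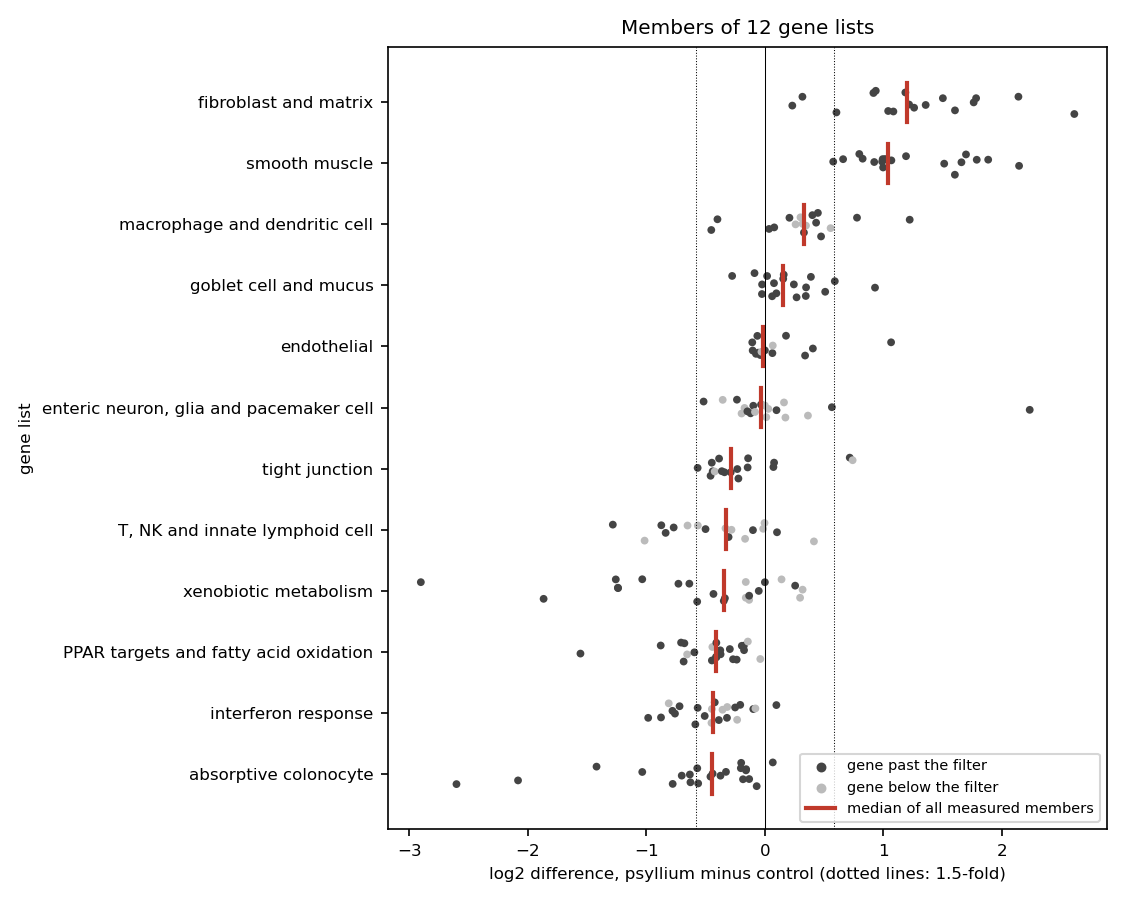
Log2 difference, psyllium minus control (horizontal axis), of each measured member of 12 gene lists (vertical axis); dark points are genes past the intensity filter, pale points genes below it, and red bars list medians. Every smooth muscle and matrix member lies to the right of 0, whereas endothelial (-0.01) and neuronal (-0.03) medians lie at 0 and absorptive colonocyte members lie mostly to the left.

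Genes of mature absorptive colonocytes were lower, and goblet cell genes slightly higher, on the psyllium array. Of 22 absorptive genes 8 were at least 1.5-fold lower and none higher, with a median of -0.45 (1.37-fold lower), below all 10000 random lists. Besides Aqp8 and Clca4a, carbonic anhydrase Car4 was 2.68-fold lower and the cytochrome Cyp2c55 2.05-fold lower. A second probe set of Cyp2c55 differed by only -0.14. Of 18 goblet and mucus genes 2 were at least 1.5-fold higher, the goblet cell regulator Spdef (1.90-fold) and Agr2, a chaperone of mucin folding (a difference of 0.59). Their median was 0.16, above the random range, and 14 of 18 members had positive differences. On the same arrays the smooth muscle median was 1.04, and pan-epithelial genes, a list added after the fixed lists were seen, had a median of -0.21 with 22 of 24 members negative.

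Tight junction genes, which seal the epithelium, had a median of -0.29, below the random range of -0.17 to 0.07. None of the 17 was 1.5-fold lower. The 2 that were 1.5-fold higher were Cldn8 (1.64-fold) and Cldn2 (0.74), which lies below the intensity filter and was named after its value was seen. By the mean of the list, -0.17, it lay inside the range. Pan-epithelial genes had a median of -0.21 and smooth muscle genes one of 1.04.

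Ion and water transport genes had a median of 0.03, inside the range, and a mean of -0.11, with members going both ways. Aqp8, Aqp4 (1.87-fold) and the sodium-proton exchanger Slc9a3 (1.63-fold) were lower, and Scnn1b, a subunit of the epithelial sodium channel, was 1.65-fold higher.

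Detoxification and lipid oxidation genes were lower, as were the absorptive colonocyte (-0.45) and pan-epithelial (-0.21) medians. Of 22 xenobiotic metabolism genes 8 were at least 1.5-fold lower and none higher, with a median of -0.34. The median was -0.60 on members past the filter, and the mean of the list was -0.56. The 8 genes included Ces2a, Ces1g, the efflux pump Abcb1a (2.39-fold) and Ces2e (2.36-fold). All 22 measured PPAR targets and fatty acid oxidation genes had negative differences, 7 of them past 1.5-fold, with a median of -0.41. The pantetheinase Vnn1 was 2.94-fold lower (145 and 49.3, the latter below the filter's intensity), the carnitine carrier Slc25a20 1.84-fold, the receptor Ppara 1.63-fold and the fatty acid binding protein Fabp2 1.61-fold. Both list medians lay below all 10000 random lists. Antioxidant genes had a median of -0.25, with 3 of 14 past 1.5-fold: the quinone reductase Nqo1 (1.75-fold lower), catalase, Cat (1.64-fold), and Srxn1 (1.52-fold). Nuclear-encoded oxidative phosphorylation genes had a median of -0.19, no larger in size than the pan-epithelial one, and 24 of 25 had negative differences. Of these Atp5b and Cycs differed by -0.16 and -0.20.

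Lists tied to short-chain fatty acids and sterols lay inside the random range. The fatty acid sensing, uptake and ketogenesis list had a median of -0.07 (-0.16 on members past the filter), and its 1 member past 1.5-fold was the monocarboxylate transporter Slc16a1 (1.52-fold lower). Cholesterol synthesis genes had a median of -0.17 with none of 19 past 1.5-fold. Hmgcs1 differed by -0.25 and Insig1 by -0.37. Fatty acid synthesis genes had a median of -0.08 (-0.13 on members past the filter), with the triglyceride synthesis enzyme Dgat2 1.72-fold lower. Bile acid and sterol handling genes had a median of -0.13, with the transporter Abcc3 1.81-fold lower. The bile acid list lay below the range by its mean (-0.21) and on members past the filter (-0.23), and the cholesterol list did so against unmatched random lists.

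Interferon-response and T cell genes were lower on the psyllium array. Beside them stood medians of 1.04 for smooth muscle, 1.20 for matrix, -0.21 for pan-epithelial and -0.45 for absorptive colonocyte genes. Of 22 interferon-response genes 21 had negative differences and 7 were at least 1.5-fold lower, with a median of -0.43 (1.35-fold lower), below all 10000 random lists. Ifit1, Oasl2, Iigp1 and Rsad2, all antiviral or pathogen-restricting genes, were 1.98-fold, 1.84-fold, 1.72-fold and 1.69-fold lower, with Iigp1 and Rsad2 below the filter's intensity on the psyllium array. Of 17 T, NK and innate lymphoid genes 6 were at least 1.5-fold lower and none higher, with a median of -0.33, and of -0.63 on members past the filter. The T cell receptor subunits Cd3e and Cd3g were 2.43-fold and 1.79-fold lower, Cd7 1.83-fold and Klrd1 1.70-fold. B and plasma cell genes had a median of -0.18, with 3 of 17 members past the filter. Ighm differed by -0.21 and Jchain by 0.23, and the other probe sets of Ighm past the filter ranged from -1.37 to 0.52. The antigen receptor segments past the filter, 16 genes, had a median of 0.23. MHC class II genes had a median of -0.23, with H2-Ab1 at -0.17 and H2-Eb1 at -0.41, and on members past the filter they lay inside the range.

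Among antimicrobial genes 4 of 21 were at least 1.5-fold lower and none higher, with a median of -0.17, beside the pan-epithelial median of -0.21. After Saa3 and Reg3g these were lysozyme, Lyz1 (1.84-fold), and Reg1 (1.75-fold). After further quantile normalisation the list median, -0.13, lay inside the range. Inflammatory cytokines and chemokines had a median of -0.08, inside the range, and the 5 of 26 past the filter had one of -0.0041. Il18 was 2.29-fold and Ccl5 1.96-fold lower, whereas cyclooxygenase 2, Ptgs2, was 2.25-fold and the alarmin Il33 1.85-fold higher. Granulocyte and mast cell genes had a median of -0.14, with 2 of 18 past the filter and the mast cell protease Mcpt1 1.65-fold lower. This list kept its place below the range under 2 of 5 alternatives.

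Heat shock genes differed by little. Their median was 0.09, at the edge of the random range, and this position held under 1 of 6 alternatives. That 1 was the use of members past the filter, which repeats the main value because all 17 members were past it. The mean of the list was 0.14, and with the mean of probe sets the median was 0.030. None of 17 was 1.5-fold lower, and the 3 that were 1.5-fold higher were the small heat shock proteins Cryab (1.91-fold), Hspb8 (1.64-fold) and Hspb1 (1.58-fold). The mean of the probe sets of Cryab was 0.67, but its other probe set lay below the intensity filter. These 3 genes are also abundant in muscle, and the smooth muscle list had a median of 1.04, with 17 of 18 members at least 1.5-fold higher. Endoplasmic reticulum stress genes had a median of 0.16, above the random range, with none of 17 past 1.5-fold. The goblet cell and mucus list, of a secretory cell type, also had a median of 0.16. In the endoplasmic reticulum stress list Hsp90b1 differed by 0.25 and Canx by -0.13.

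Proliferation and crypt base genes lay inside the random range. None of 30 proliferation genes was past 1.5-fold, and their median was -0.07, with Mki67 at -0.07 and Pcna at 0.04. Crypt base and Wnt target genes had a median of 0.02 and a mean of 0.091, with Cd44 (1.88-fold) and Nkd1 (1.77-fold) higher. Enteroendocrine genes had a median of 0.10, inside the range, with somatostatin, Sst, 1.95-fold lower. The median was -0.0625 on members past the filter and 0.14, above the range, without the intensity trend, so it had no settled direction. Tuft cell genes had a median of -0.15 and a mean of -0.089 with none of 13 past 1.5-fold, and that position below the range held under 2 of 6 alternatives. Dclk1 differed by 0.40 and Rgs13 by -0.18.

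Lists chosen to follow the sample itself were as follows. Cytosolic ribosomal protein genes had a median of -0.04, with Rpl4 at -0.04 and Rps6 at 0.04. Pancreatic acinar genes had a median of 0.11 with 3 of 13 members past the filter. Small intestine enterocyte and Paneth cell genes, of which 13 of 17 were past the filter in this colon RNA, had a median of -0.26, and of -0.39 on members past the filter, beside -0.45 for absorptive colonocyte and -0.21 for pan-epithelial genes. Apoa4 was 2.31-fold and the defensin Defa24 1.89-fold lower. Posterior Hox genes had a median of 0.17 and anterior and central ones a median of -0.04, both inside the range. Hoxd10 differed by 0.55 and Hoxb9 by 0.10, whereas Hoxb6 differed by -0.17 and Hoxb5 by -0.24. Circadian clock genes had a median of -0.19, with the clock repressor Nr1d1 2.09-fold lower and Npas2 1.76-fold higher. Immediate early genes had a median of -0.18, with Zfp36 (1.59-fold) and Fos (1.55-fold) lower and Ccn2 (2.66-fold) and Ccn1 (2.08-fold) higher. The mean of the 2 probe sets of Ccn2 was 0.65, but the other one lay below the intensity filter. By their means, -0.13 and -0.04, the clock and immediate early lists lay inside the range. The erythrocyte list had 1 measured member, Slc4a1, at 0.05.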

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

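The pan-epithelial test in this part was written before that list's values were looked at. The tests on the outer muscle wall, on endothelial and goblet genes, on the intensity trend, on Hox genes and on the clock were chosen after the list values were seen.

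Signals were also present in probe sets that the comparison left out. Of 5148 probe sets past the filter that name no gene here, 73 were at least 2-fold higher and 61 at least 2-fold lower on the psyllium array. Of 820 that name several genes, 4 were higher and 6 lower by as much.

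Smooth muscle and matrix genes were higher, with medians of 1.04 and 1.20. A lower epithelial share would lift all cell types outside the epithelium alike. The 12 endothelial genes past the filter had a median of -0.019 (95% bootstrap interval over genes -0.07 to 0.26), under the bound of 0.52 that this explanation needed. The endothelial list had been seen when that bound was set, so this describes the arrays and is no independent test. Macrophage and dendritic cell genes had a median of 0.33 and T, NK and innate lymphoid genes one of -0.33. Some lymphocytes lie within the epithelium and would fall with it, so the value of -0.33 cannot decide this question. The endothelial and macrophage medians, both far under 1.04, argue against a lower epithelial share as the whole cause, not as a part of it. A trend of the difference with intensity is also argued against as the whole cause, because it was small. Its removal moved genes by a median of 0.033 and left a smooth muscle median of 1.08. A larger share of the outer muscle wall stays open: the 9 neuronal, glial and pacemaker genes past the filter had a median of -0.10, but the interval, -0.24 to 0.56, reached the bound. With 9 genes a resampled median is the value of 1 gene. The upper end matches the difference of the pacemaker cell gene Ano1, 0.56, named after its value was seen. Ano1 is therefore no support apart from the interval. The largest difference in that list was that of Vip, 2.23. A response of muscle and stroma to the diet is the biological alternative, and with so few such genes and 1 array per diet the share of muscle wall and the diet cannot be told apart.

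Absorptive colonocyte genes were lower, with a median of -0.45. A lower epithelial share as the whole cause is argued against by goblet cell genes, whose median was 0.16 (0.04 to 0.35) where -0.22 or less was needed. The goblet list had been seen when that bound was set, so this describes the arrays and is no independent test. As part of the cause a lower epithelial share stays open, since 24 pan-epithelial genes had a median of -0.21 with an interval, -0.28 to -0.09, that holds the same bound. A more distal piece of colon stays open as an explanation. Posterior Hox genes exceeded anterior and central ones by 0.21 (0.08 to 0.46). This was a percentile of 95.02 among pairs of random lists against an upper limit of 95, so near that another draw may fall short of it. That limit, chosen after the Hox medians were seen, was looser than the central 95% used for the lists. By the central 95% the contrast lay inside the random range, so it cannot decide this question. Only 3 of 12 posterior Hox genes were past the filter, so this contrast rests mostly on dim probe sets. An effect of the diet on these cells stays open and untested.

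The 8 clock output genes had a median of -0.29, all negative and 1 past 1.5-fold, beside a pan-epithelial median of -0.21. Of 5 genes of the opposite phase 4 had positive differences. All 8 and all 5 already belonged to the fixed lists, which include the circadian clock list. Those values had been seen when the arms were formed, so the signs within each arm are no independent evidence. RNAs from different phases of the daily clock would need the opposite genes to be higher. Their median was 0.18 (-0.0055 to 0.82), inside the random range of -0.26 to 0.24, so these 5 genes leave that explanation open. An effect of the diet on the clock was not tested.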

How the results depend on the processing

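No paired analysis was possible because each diet has 1 array. For the same reason no array could be left out and no other split of the samples made. The 117 higher and 57 lower genes became 447 and 268 at 1.5-fold and 35 and 12 at 3-fold. Without the filter 100 genes were lower. The other alternatives stayed within 1.5 times of these counts. Of 224 recomputed list values 181 kept their place and size, and none of the lists standing apart changed sign. The 181 include lists with all members past the filter, for which that alternative repeats the main value. Of 318 recomputed values of named genes 4 moved by over 0.25, all with the mean of the probe sets, and none reversed. The 4 were those of Clca4a, Cryab, Cyp2c55 and Ccn2. Of these only Cyp2c55 had its other probe set past the filter, so the other means include a dim probe set. Most named genes have 1 probe set, so that alternative could not move them. The 2 rescalings moved genes by medians of only 0.023 and 0.033. The count therefore says little about how stable the named values are. The cause of the changes below was not tested. By the mean of the list, the tight junction value became -0.17, heat shock 0.14, tuft cell -0.089, adipocyte 0.092, circadian clock -0.13 and immediate early -0.041, all inside the random range, and bile acid -0.21, outside it. The mean also moved absorptive colonocyte to -0.62, ion and water transport to -0.11, xenobiotic to -0.56, crypt base to 0.091, enteroendocrine to 0.027, T and NK cell to -0.42, smooth muscle to 1.24, endothelial to 0.12, neuron and glia to 0.088 and small intestine to -0.35. On members past the filter, MHC class II (-0.17), tuft cell (-0.12) and adipocyte (0.046) lay inside the range and bile acid (-0.23) outside. There short-chain fatty acid genes moved to -0.16, xenobiotic to -0.60, cytokines to -0.0041, interferon to -0.51, enteroendocrine to -0.0625, T and NK cell to -0.63 and small intestine to -0.39. Further quantile normalisation put heat shock (0.067), antimicrobial (-0.13), granulocyte and mast cell (-0.10) and adipocyte (0.16) inside. Without the intensity trend, heat shock (0.12), tuft cell (-0.15), granulocyte and mast cell (-0.12) and adipocyte (0.15) lay inside and enteroendocrine (0.14) outside. With the mean of probe sets heat shock (0.030) lay inside and matrix moved to 1.13. Against unmatched random lists heat shock (0.088), tuft cell (-0.15) and granulocyte and mast cell (-0.14) lay inside and cholesterol synthesis (-0.17) outside. B and plasma cell (3 of 17), granulocyte and mast cell (2 of 18), pancreatic acinar (3 of 13) and posterior Hox genes (3 of 12) had too few members past the filter to give a value there. Their values rest mostly on dim probe sets.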

Other observations

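A hypothesis raised after the data were seen concerned YAP and TEAD, transcriptional regulators that respond to mechanical tension. It was that genes induced through them were higher together with the matrix genes. The reason was that Ankrd1 (5.22-fold) and Ccn2 (2.66-fold, or a log2 difference of 0.65 by the mean with a probe set below the filter) were. A list of other known targets was written without those 2 genes and before its values were looked at, except that Ccn1 also belongs to the immediate early list, whose values had been seen. The 20 measured members had a median of 0.37, above all 10000 random lists, and 15 of them had positive differences. Ccn1 (1.06) and Axl (0.78) were highest and Crim1 (-0.35) lowest. The condition set beforehand for the hypothesis, a median above 95% of random lists, was thus met. Random lists were matched on expression and not on cell type, and smooth muscle and matrix medians were 1.04 and 1.20. That condition therefore cannot tell induced targets from a larger share of muscle and stroma. The bound set beforehand against it, an interval that ends below 0.60, was met as well, since the 95% bootstrap interval over genes ran from 0.11 to 0.50. The bound argues against a difference of the set comparable with the matrix median of 1.20, while a smaller one stays open.

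The difference of greatest size over all 41345 probe sets lay in a second probe set of Kcnma1, a potassium channel gene expressed in smooth muscle, with an intensity of 1014 on the control array and 24.8 on the psyllium array. The other Kcnma1 probe set went the opposite way, with 316 and 528, a difference of 0.74. This gene was named after its values were seen.

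Identical values on both arrays occurred for 559 genes, 84 of them past the filter, and for 8 list members.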
